A study of Canis lupus familiaris with 2 samples.

How the data were processed

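RNA from J3T-1 and J3T-2 was hybridized to 1-colour Affymetrix canine expression arrays, 1 array per subclone. Per the labels' protocols, both subclones were grown in serum-containing DMEM, total RNA was purified on RNeasy columns, and biotin-labelled cRNA was made from 250 ng of RNA with a 3' IVT kit. The deposited values are MAS5 signal intensities on a linear scale, 1 per probe set and array, MAS5 being the tool that the submitters' processing notes name. Its version, its scaling target and its detection calls are not given in the sources used here. The values bear on this: the 2% trimmed means of the arrays were 103.7 in J3T-1 and 117.2 in J3T-2, so the arrays do not share a trimmed mean. MAS5 takes mismatch probes as background and leaves values near background noisy, which is why a floor was set before ratios were taken.

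The table held 43035 probe sets, 111 of them controls. Through the array annotation, 29254 of the 42924 other probe sets had 1 gene symbol, 439 had several and 13231 had none; genes were named from probe sets with 1 symbol only. These gave 15115 genes. Signals below each array's median over non-control probe sets were set to that median (the floor, 19.0 in J3T-1 and 22.0 in J3T-2). Each gene was represented by its probe set with the highest mean log2 signal, and a gene counted as measured when that probe set was above the floor on at least 1 array. This left 9433 genes, 8266 above the floor on both arrays, 601 in J3T-1 only and 566 in J3T-2 only. The log2 ratio was taken as J3T-2 over J3T-1 of the deposited signals without further scaling. Where 1 array was at the floor, the fold is a lower bound, written "at least". No fold is given where the bound was under 1 or both arrays were at the floor.

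With 1 array per subclone there are no replicates, so no test between the subclones, no p-value and no replicate SD was possible. The number of arrays limits the precision. Genes were counted by a rule of size, a fold of at least 2. The only error estimate is the SD of the log2 ratio between probe sets of the same gene. It is technical and holds no biological spread. For 32 gene lists, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on signal in 10 classes. A list below the 2.5th or above the 97.5th percentile is called outside the random range, as a description of these 2 arrays. List medians are given relative to the median of all measured genes unless stated otherwise. Folds and log2 ratios of single genes are not, so they hold the shift of all genes towards J3T-2 (0.167 in log2). Genes just over 2-fold higher in J3T-2 fall under 2-fold once that shift is taken off, and genes just under 2-fold higher in J3T-1 rise over it.

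The genes named were fixed by rule: in each direction the 12 largest folds among genes above the floor on both arrays whose other probe sets went the same way, the 5 largest lower bounds, up to 4 members of each list by size of the log2 ratio, and FGF13, ANXA2, VEGFA, MMP2, CD44, PDGFRA, GFAP, SOX2 and NES. FGF13 and ANXA2 were included because the laboratory has published on them in these subclones. Hypothetical genes were skipped in the first 2 parts. Further list members named to complete a count were chosen after their values were seen.

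Chromosomes were taken by gene from the assembly UU_Cfam_GSD_1.0, used only to group neighbouring genes, since no genome build is named for the array values. Of the measured genes, 8915 had a chromosome there. Values were recomputed under 8 other settings, namely 3 scalings (centring on the median, quantile normalization, loess with a span of 0.3), floors at the 25th and 75th percentiles, no floor with a pseudocount of 16, the median over a gene's probe sets, and leaving out probe sets with an _x_at or _s_at suffix. The 2 added after the data were seen were leaving out chromosomes 9, 10 and 14 and centring on the hybridization controls. Random lists numbered 2000 per alternative. The size rule, the gene lists, the naming rule and the first 8 settings were chosen before the data were examined.

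The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The size rule was tested on simulated data for J3T-2 against J3T-1, with a noise SD of 0.261 in log2 over 9044 genes. It called 100 of 100 planted 3-fold genes, 11 of 100 planted 1.5-fold genes and 1 of 8844 unchanged genes. The planted genes were all brighter than the median measured gene, and every probe set had the same noise. That noise holds no spread between arrays or cultures and is not raised for dim genes. The calls among unchanged genes are therefore no error rate for the counts below. Of 20 null lists, 1 lay outside the random range.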

Results

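J3T-1 and J3T-2 are subclones of a single parental canine glioma cell line that differ in how they invade and in angiogenesis. The comparison asks which transcripts differ between them in culture. Each subclone was profiled on 1 array, so every value below is a single measurement without replicates. Signal ranged up to 9433 in J3T-1 and 9837 in J3T-2, and the medians were 19.0 and 22.0. Across the 19829 probe sets above the floor on both arrays, log2 signals correlated with r = 0.937, a correlation across probe sets, which are not independent replicates. The 3' over 5' signal of the actin control was 0.96 in J3T-1 and 0.85 in J3T-2, and that of GAPDH was 0.98 and 1.1. A second control set gave 1.92 and 1.61 for actin and 1.44 and 1.37 for GAPDH.

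Angiogenesis-promoting ligands and chemokines, cytokines and complement were among the 8 gene lists that lay below matched random lists in J3T-2 over J3T-1, and extracellular matrix and proneural and neural stem cell genes among the 5 above. Chemokines, cytokines and complement came inside the random range with the floor at the 75th percentile and with no floor. Extracellular matrix did so with no floor. Of 9433 measured genes, 687 (7.28%) were at least 2-fold higher in J3T-2 and 329 (3.49%) at least 2-fold higher in J3T-1, and 8417 lay within 2-fold. At least 8-fold differences were seen for 38 genes higher in J3T-2 and 26 higher in J3T-1. Among the 2-fold genes, 165 higher in J3T-2 and 78 higher in J3T-1 were at the floor on the other array. The median log2 ratio of all measured genes was 0.167 towards J3T-2, and with ratios centred on it the counts were 470 and 436, so that the share of calls higher in J3T-2 went from 67.6% to 51.9%. The excess turned over under quantile normalization (438 and 467, or 48.4%) and under loess (438 and 465, or 48.5%). Probe sets of the same gene differed by an SD of 0.261 in log2 ratio (root mean square over 4580 genes). Of 382 genes at least 2-fold apart with several probe sets above the floor, 374 had all of them in 1 direction.

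The endothelial proteoglycan gene ESM1 had the largest fold towards J3T-1 among genes above the floor on both arrays, with a signal of 2091 against 55.4 (37.7-fold). The calcium-binding protein gene S100A4 was 23.6-fold higher in J3T-1, the activin antagonist FST 16.3-fold, PHLDB2 16.02-fold, the transmembrane glycoprotein gene GPNMB 15.8-fold, the ERK phosphatase gene DUSP5 12.3-fold, the vasodilator peptide gene ADM 11.4-fold and the cell-cycle inhibitor CDKN1A 10.99-fold (6.77-fold by its other probe set above the floor). S100A2 was 8.4-fold, the VEGF receptor gene FLT1 8.3-fold (3.13-fold by 1 of its 3 probe sets), APBB2 8.27-fold (4.46-fold by its other probe set) and ANKS1B 7.92-fold higher. Of genes at the floor in J3T-2, the chemokine genes CXCL8 and CCL2 were at least 58.95-fold and at least 23.9-fold higher in J3T-1, the hyaluronan synthase gene HAS2 at least 20.6-fold, ANK3 at least 13.9-fold and DNM3 at least 12.97-fold.

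On the J3T-2 side the metalloprotease inhibitor TIMP3 was 32.6-fold higher, against 6.0-fold by its other probe set above the floor. The prostaglandin E synthase gene PTGES was 32.4-fold, the matricellular gene SPARCL1 25.5-fold and the neuronal membrane glycoprotein gene GPM6A 23.9-fold higher. FGF13, an intracellular FGF-family protein that binds microtubules and sodium channels, had a signal of 20.4 in J3T-1 and 414.1 in J3T-2 (20.3-fold), and its other probe set above the floor gave 3.48-fold. FAM107A was 17.7-fold (3.89-fold and 5.86-fold by its other 2 probe sets above the floor), the ketone-body enzyme gene OXCT1 17.2-fold, SBSPON 15.3-fold, the acetyltransferase gene KAT2B 14.3-fold, the guidance ligand SLIT3 13.03-fold, TMEM47 11.8-fold (7.07-fold by its other probe set) and GNG2 11.5-fold higher. The J3T-1 signals of SLIT3 (19.9), FGF13 (20.4), OXCT1 (20.5), FAM107A (21.0), PTGES (21.5) and TIMP3 (22.5) were close to the floor of 19.0, so their folds rest on a dim value, and the other probe sets of OXCT1 and PTGES were at the floor in J3T-1. At the floor in J3T-1 were the matrix glycoprotein gene EFEMP1, at least 64.0-fold higher in J3T-2, ECRG4 at least 53.2-fold, the monoamine oxidase gene MAOA at least 32.0-fold, FEZ1 at least 27.1-fold and the retinoic acid receptor gene RARB at least 25.2-fold, whose probe set above the floor on both arrays gave 13.94-fold.

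**Figure D1:**
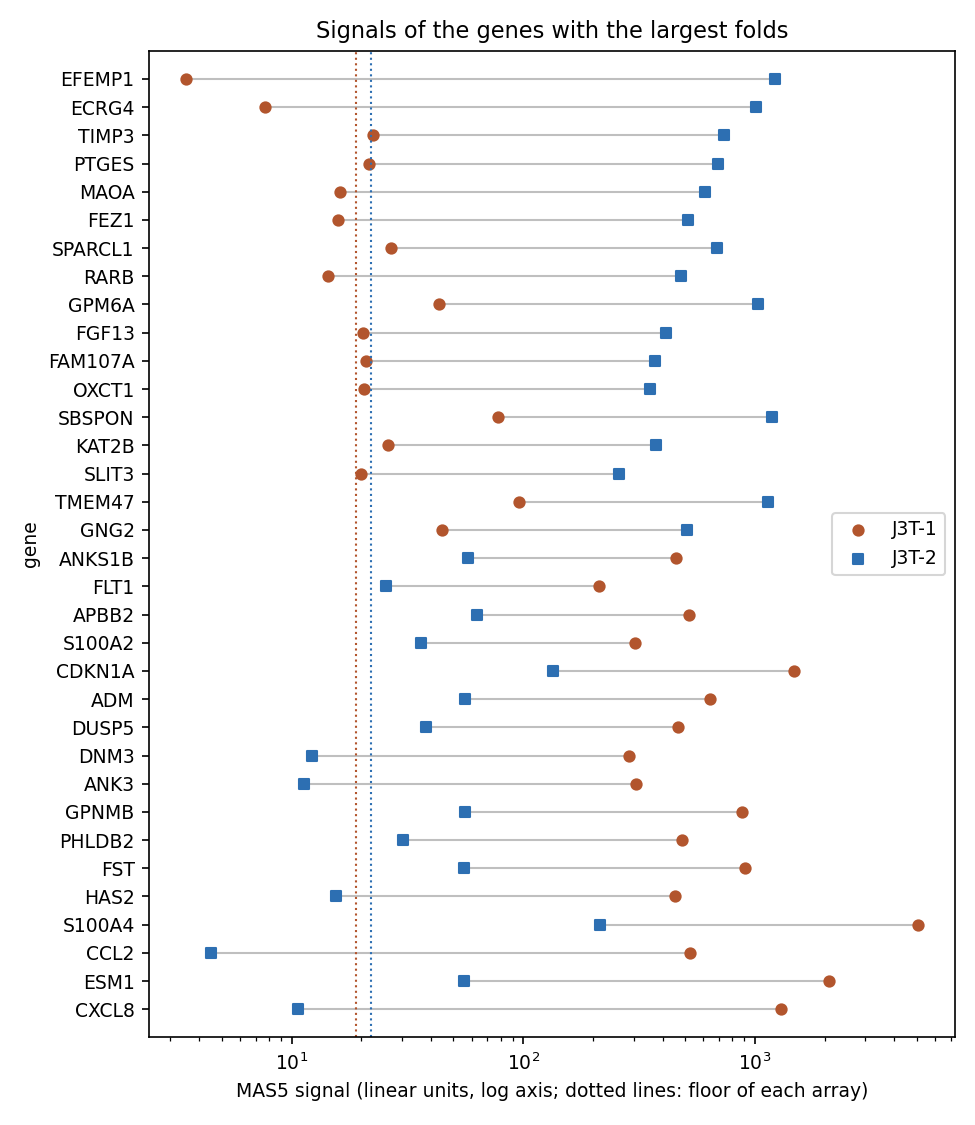
MAS5 signal (linear units on a log axis) of the genes with the largest folds, 1 array per subclone, with J3T-1 as circles, J3T-2 as squares and the floors of the arrays (19.0 and 22.0) as dotted lines. Points left of their own floor are not measured levels, as for EFEMP1 in J3T-1 and CXCL8 in J3T-2.

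Ligands that promote angiogenesis were lower in J3T-2 as a group. Of 24 measured members, 9 were at least 2-fold higher in J3T-1 and 4 at least 2-fold higher in J3T-2, and their median lay -0.97 in log2 from that of all genes (percentile 0.0 of random lists), a distance that shrank to -0.56 with the floor at the 25th percentile, -0.53 without _x_at and _s_at probe sets (the suffix filter) and -0.21 with no floor. Besides CXCL8, ESM1, CCL2 and ADM, the growth factor VEGFA was 4.82-fold higher in J3T-1, with signals of 1077.5 and 223.7, and its other probe set gave 2.44-fold. The 4 members at least 2-fold higher in J3T-2 were ANGPT1 (7.93-fold), PTN (4.03-fold), TGFB2 (3.9-fold) and ANGPTL4 (2.17-fold). Angiogenesis inhibitors were also lower in J3T-2 at their median (-0.56, percentile 0.04, 10 measured): SERPINF1, which encodes PEDF, was 3.5-fold, SEMA3A 4.11-fold (2.17-fold by its other probe set) and CXCL14 at least 5.3-fold higher in J3T-1, while TIMP3 and SPARC (2.34-fold) were higher in J3T-2. With the floor at the 75th percentile this list's plain median turned to 0.09 over 6 genes, and CXCL14 to 0.05. The list also came inside the random range with the floor at the 25th percentile (-0.27) and with no floor (-0.14).

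Hypoxia-inducible and glycolysis genes were likewise lower in J3T-2, with a median of -0.49 (percentile 0.0, 38 measured), 8 of them at least 2-fold higher in J3T-1 and 1, the oxygen sensor gene EGLN3 (2.31-fold), higher in J3T-2. Without its 8 largest changes the list had a median of -0.41 (percentile 0.0, 30 genes). This is no separate support, since the same list was cut by its own values and a median changes little when extremes are dropped. A list of 22 further hypoxia-inducible genes, drawn up after the data were seen, had a median of -0.03 (percentile 39.12) and 0 at least 2-fold apart. The collagen cross-linking enzyme gene LOX was 6.84-fold, the pyruvate dehydrogenase kinase gene PDK1 5.35-fold, the glucose transporter gene SLC2A3 4.0-fold and BHLHE40 2.48-fold (1.57-fold and 1.48-fold by its other 2 probe sets) higher in J3T-1. Chemokines, cytokines and complement had a median of -0.50 (percentile 0.02, 15 measured), with 5 members at least 2-fold higher in J3T-1, among them the death ligand TNFSF10 (3.91-fold), and CXCL16 (2.82-fold) and SERPING1 (2.51-fold) higher in J3T-2. Its plain median turned to 0.05 over 7 genes with the floor at the 75th percentile, and it came inside the random range with no floor (-0.11). Interferon-stimulated genes stayed inside the random range (percentile 90.1, 26 measured): PSMB8 and IFI35 were both 2.3-fold higher in J3T-2 (IFI35 1.52-fold to 1.8-fold by its other probe sets), and SAMD9L 2.24-fold and OAS2 2.03-fold higher in J3T-1.

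Mesenchymal genes and the annexin and S100 families were also lower in J3T-2. The mesenchymal list had a median of -0.35 (percentile 0.02, 29 measured), with 8 members at least 2-fold higher in J3T-1, led by LOX and the AP-1 subunit gene FOSL1 (4.2-fold), and 4 at least 2-fold higher in J3T-2, namely TGFBI (at least 12.1-fold), STAT3 (5.18-fold, or 2.69-fold to 4.56-fold by its other probe sets), WWTR1 (3.02-fold) and CDH2 (2.1-fold). Annexins and S100 proteins had a median of -0.35 (percentile 0.08, 18 measured). S100A16 was 6.63-fold and ANXA3 2.04-fold higher in J3T-1 beside S100A4 and S100A2, and S100A1 was 3.65-fold higher in J3T-2. ANXA2 had signals of 9433.3, the highest of the J3T-1 array, and 7834.0. Its other 2 probe sets gave 1.04-fold towards J3T-2 and 1.37-fold towards J3T-1. With no floor the medians of the mesenchymal and the annexin list were -0.20 and -0.16. CD44, the hyaluronan receptor, had a log2 ratio of -0.22, with 1 of 3 probe sets the other way.

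Extracellular matrix genes were higher in J3T-2 as a group, with a median of 0.45 (percentile 100.0, 39 measured), 14 members at least 2-fold higher in J3T-2 and 7 at least 2-fold higher in J3T-1. The former included EFEMP1, SPARCL1, TGFBI and the fibrillar collagen gene COL1A1 (8.12-fold), and the latter COL14A1 (5.52-fold) and VCAN (4.67-fold). Its median was 0.25 without the genes of chromosomes 9, 10 and 14 and 0.84 with the suffix filter. Without a floor and with a pseudocount of 16 over 59 genes it was 0.07, at percentile 91.25, inside the random range. Contractile genes had a median of 0.40 (percentile 100.0, 30 measured), 7 of them at least 2-fold higher in J3T-2, among them smooth muscle actin ACTA2 (6.17-fold), PDLIM3 (at least 5.22-fold) and the focal adhesion gene VCL (4.07-fold), and 2 at least 2-fold higher in J3T-1, FHL2 (3.21-fold) and MYOCD (2.21-fold). The J3T-1 signal of ACTA2 (22.8) was close to the floor of 19.0.

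Genes of neural progenitors were higher in J3T-2. In the proneural and neural stem cell list 9 of 21 measured genes were at least 2-fold higher in J3T-2 and 0 at least 2-fold higher in J3T-1, with a median of 0.43 (percentile 99.8). GPM6A, the differentiation inhibitor gene ID4 (at least 7.16-fold), the fatty acid binding protein gene FABP7 (at least 4.32-fold) and the transcription factor gene POU3F2 (at least 3.17-fold) had the largest differences. The stem cell factor SOX2 was 2.9-fold and the receptor gene PDGFRA 2.26-fold higher, and the intermediate filament gene NES had a log2 ratio of 0.33. The median of this list was 0.13 with no floor and 1.43 with the suffix filter. Astrocyte markers reached percentile 96.0 (14 measured), with ACSBG1 at least 13.3-fold and the glutamate transporter gene SLC1A3 3.11-fold higher in J3T-2 and the gap junction gene GJA1 2.48-fold higher in J3T-1. With the floor at the 75th percentile the list's median went from 0.22 to 0.04 (percentile 60.75). GFAP was at the floor on both arrays.

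Neuronal and oligodendrocyte markers lay inside the random range in the main setting, at percentiles 84.1 (7 measured) and 78.0 (5 measured), but their direction depended on the floor. Neuron markers were at -0.37 (percentile 2.65, 26 genes) with the floor at the 25th percentile and at -0.14 (percentile 1.05, 35 genes, outside the range) with no floor, and oligodendrocyte markers at -0.13 and -0.15. The neurofilament gene NEFL was 11.1-fold and THY1 4.47-fold higher in J3T-2, and UCHL1 2.48-fold higher in J3T-1, while SYT1 was close to the floor. CNP was 2.59-fold higher in J3T-2, QKI had a log2 ratio of 0.42, and MBP was at least 1.36-fold higher in J3T-1. The list of neuronal migration and microtubule regulators lay at percentile 87.8 (25 measured), with 5 members at least 2-fold higher in J3T-2 and 0 in J3T-1: FGF13, DCLK2 (at least 4.74-fold), MAP2 (4.71-fold), DPYSL2 (2.35-fold, 1 probe set the other way) and DPYSL3 (2.07-fold).

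Wnt signalling genes had a median of 0.39 (percentile 99.96, 25 measured), with WNT5B and DKK3 both 3.07-fold and the co-receptor gene LRP6 2.24-fold higher in J3T-2, and WNT7A at least 2.79-fold and LGR4 2.01-fold higher in J3T-1. TGF-beta and BMP signalling genes had a median of 0.26 (percentile 99.3, 33 measured), with 9 members at least 2-fold higher in J3T-2, among them BMP6 (at least 8.35-fold), the pseudoreceptor gene BAMBI (5.55-fold) and TGFB2, and 4 at least 2-fold higher in J3T-1, among them FST. With the floor at the 25th percentile this list no longer lay outside the random range, and with no floor the Wnt and TGF-beta medians were 0.10 and 0.17. Fibroblast growth factors and their receptors, at percentile 37.3 (16 measured), went both ways: FGFR2 was 3.96-fold higher in J3T-2 and FGF14 6.97-fold higher in J3T-1. Growth factor receptors lay at percentile 6.79 (26 measured), came outside with the floor at the 25th percentile (0.7) and the suffix filter (1.02) and turned to 0.07 with the floor at the 75th, with the receptor kinase gene AXL 5.71-fold higher in J3T-1 and IGFBP2 (at least 3.37-fold) and NTRK2 (3.14-fold, or 10.02-fold by its other probe set above the floor) higher in J3T-2. Homeobox genes lay at percentile 93.9 (14 measured), with PRRX2 (5.26-fold), MEIS2 (2.38-fold, or 3.81-fold by its other probe set) and HOXD10 (2.13-fold, or 1.38-fold) higher in J3T-2 and PRRX1 at a log2 ratio of 0.93. The list was at -0.04 with no floor. It lay outside the range without the 3 chromosomes (0.76, over only 7 genes) and with the median over probe sets (percentile 97.8).

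Integrin subunits lay at percentile 5.6 (16 measured), with ITGA3 (at least 8.69-fold), ITGA2 (6.55-fold), the fibronectin receptor subunit gene ITGA5 (4.11-fold, or 2.31-fold by its other probe set) and ITGA7 (3.76-fold) higher in J3T-1 and ITGB3 (6.52-fold) higher in J3T-2. The integrin list came outside with the floor at the 75th percentile (percentile 0.05), the median over probe sets (0.7) and without chromosomes 9, 10 and 14 (0.3), and turned to 0.03 with the floor at the 25th percentile and 0.06 with no floor. Cell-cell adhesion molecules had a median of -0.25 (percentile 0.76, 22 measured) with 5 members at least 2-fold higher in J3T-2, led by CHL1 (at least 4.86-fold), NRCAM (4.83-fold) and CDH11 (2.83-fold), and 4 at least 2-fold higher in J3T-1, led by CDH18 (at least 3.63-fold). This list lay outside the random range in every setting, at -0.15 with no floor. Proteases and their inhibitors lay at percentile 15.0 (22 measured): FAP was at least 8.07-fold and the collagenolytic protease gene CTSK 2.75-fold higher in J3T-1, and the plasminogen activator gene PLAT 4.4-fold higher in J3T-2. The protease list was at 0.08 with the floor at the 75th percentile and outside the range with the median over probe sets (percentile 0.25). The gelatinase gene MMP2 had signals of 34.8 and 35.3. Axon guidance genes lay at percentile 5.08 (26 measured), with PLXND1 5.06-fold, SEMA3A and EPHA2 (2.6-fold) higher in J3T-1 and SLIT3 and SEMA6D (2.24-fold) higher in J3T-2. EPHA2 had a log2 ratio of 0.01 with the floor at the 75th percentile, and the list was at 0.13 with the floor at the 25th percentile and 0.02 with no floor.

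Of the microglia and leukocyte markers (percentile 34.8, 9 measured), 0 were at least 2-fold apart; CORO1A, CD68 and TREM2 were near the floor, and CTSS had signals of 60.7 and 69.7. Endothelial markers had a median of -0.56 (percentile 0.1, 10 measured), with FLT1 higher in J3T-1, SELP at least 4.04-fold higher in J3T-2, CD34 1.77-fold higher in J3T-1 and EGFL7 1.7-fold (2.57-fold by its other probe set) higher in J3T-2. This list returned inside the random range with the floor at the 25th percentile (-0.37) and with no floor (-0.14). Fibroblast and pericyte markers lay at percentile 92.8 (14 measured), and went from COL1A1 and ACTA2 higher in J3T-2 to S100A4 and FAP higher in J3T-1. Their median, 0.22 in the main setting, was -0.27 with the floor at the 25th percentile, -0.09 with no floor and 0.03 without the 3 chromosomes, and the list lay outside the range with the floor at the 75th percentile (percentile 99.4) and the suffix filter (100.0).

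Proliferation, stress and housekeeping genes lay inside the random range in the main setting. Cell cycle genes were at percentile 96.4 (56 measured), and outside with the median over probe sets (97.55) and the suffix filter (99.25), with CDK2 2.91-fold and MYBL2 2.28-fold (1.93-fold by its other probe set) higher in J3T-2 and CDKN1A and CDKN3 (2.65-fold) higher in J3T-1. DNA repair and drug resistance genes lay at percentile 34.4 (16 measured), with the efflux pump gene ABCB1 5.75-fold higher in J3T-1, NF1 2.07-fold (1.51-fold by its other probe set above the floor) higher in J3T-2 and BRCA1 at a log2 ratio of 0.97. Cholesterol genes lay at percentile 34.5 (21 measured): INSIG1, which restrains sterol synthesis, was 4.54-fold higher in J3T-1, and MSMO1 (-0.85), EBP (-0.80) and HSD17B7 (0.75) were within 2-fold. Stress genes of the endoplasmic reticulum lay at percentile 9.32 (31 measured), with CHAC1 2.61-fold (1.74-fold by its other probe set) higher in J3T-2, and DNAJB9 (-0.97, or -1.16 by its other probe set), ATF3 (-0.82) and PPP1R15A (0.73, 1 probe set the other way) within 2-fold by their brightest probe set. Ribosomal protein genes lay at percentile 3.7 (50 measured), with a plain median of 0.03 that was -0.14 relative to all genes. The list came outside with the floor at the 75th percentile (1.9), but lay at percentile 50.3 under quantile normalization, 30.98 under loess and 42.65 with the suffix filter. RPS10 (2.81-fold) and RPL22 (1.99-fold) were higher in J3T-2. RPL27 (1.31-fold) and RPL12 (1.22-fold) had log2 ratios of 0.39 and 0.29, within the probe set spread of 0.261 from the median of all genes (0.167). Of 16 housekeeping genes (percentile 6.77), 0 were at least 2-fold apart, with B2M and TBP (1 probe set the other way) at 0.30 and PGK1 at -0.29; the non-control probe set of ACTB was dim.

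**Figure D2:**
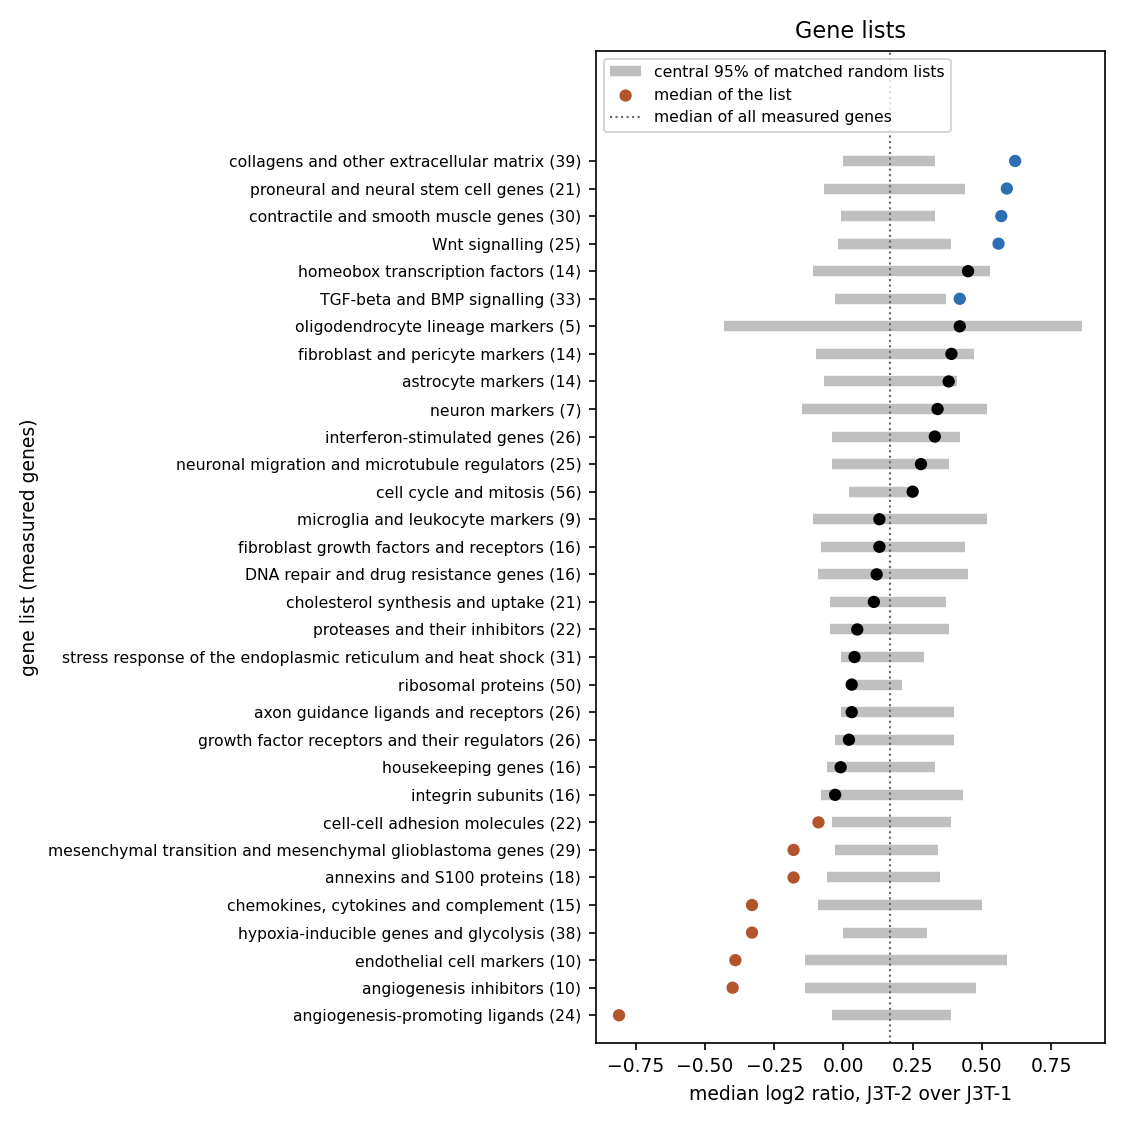
Median log2 ratio (J3T-2 over J3T-1, x axis) of each of the 32 gene lists, with the number of measured genes in brackets, as points over grey bars that hold the central 95% of matched random lists; the dotted line is the median of all measured genes (0.167), and points outside their bars are coloured. The 8 lists left of their bars are led by angiogenesis-promoting ligands and the 5 right of them by extracellular matrix.

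Neighbouring genes differed together most on 3 chromosomes. Grouped by the assembly UU_Cfam_GSD_1.0, genes of chromosome 9 had a median log2 ratio of 0.61 (486 genes above the floor on both arrays), those of chromosome 10 had 0.59 (300 genes) and those of chromosome 14 had -0.32 (131 genes). The medians of the other 36 chromosomes ran from -0.01 to 0.26. Of these, chromosome 1 (394 genes) also lay below all of 10000 random gene sets of its size, and chromosomes 27 and 4 were matched as low by only 2 and 4 sets. Of the genes at least 2-fold higher in J3T-2, 153 lay on chromosomes 9 and 10, and 10 of those higher in J3T-1 lay on chromosome 14. In the opposite direction were 16 genes on chromosomes 9 and 10 and 9 on chromosome 14. Among the 136 measured genes named by rule, 23 lie on these chromosomes, against 1057 of the 8915 measured genes with a chromosome. TIMP3, EFEMP1, ECRG4 and FHL2 are on chromosome 10, and PTGES, CCL2, SERPINF1, COL1A1, ITGA3, ITGB3, STAT3, CNP, EGFL7, PRRX2, IFI35, NF1, BRCA1, RPL27 and RPL12 on chromosome 9. GPNMB, ABCB1, SAMD9L and DNAJB9 are on chromosome 14. Of all these, FHL2, CCL2, SERPINF1 and ITGA3 went against the shift of their chromosomes, being higher in J3T-1. Without these chromosomes the median of the matrix list was 0.25 in place of 0.45, over 34 genes.

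**Figure D3:**
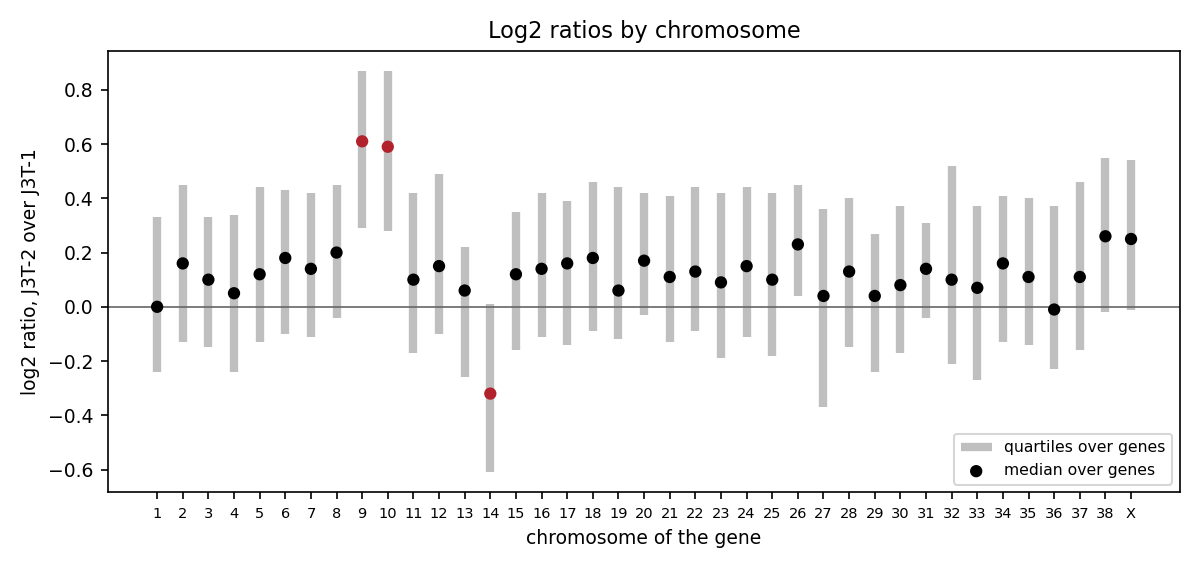
Log2 ratio (J3T-2 over J3T-1, y axis) by chromosome of the gene (x axis), with points for the median and grey bars for the quartiles over genes above the floor on both arrays. Chromosomes 9 and 10 (0.61 and 0.59) lie above, and chromosome 14 (-0.32) below, the range of the other 36 (-0.01 to 0.26).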

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

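The tests without chromosomes 9, 10 and 14 and with centring on the hybridization controls were chosen after the data were seen. No replicate could be left out, with 1 array per subclone. No paired analysis was possible because the result comes from no test between replicates. Of 136 named genes, 0 changed sign among those at least 2-fold apart under the 3 scalings, the floor at the 25th percentile, no floor, the median over probe sets or the suffix filter, under which 32 genes had no value. With the floor at the 75th percentile CXCL14 (0.05) and EPHA2 (0.01) did, lying near or under that floor on both arrays, and 30 genes had no value. Sizes were less stable: log2 ratios moved by more than the probe set spread of 0.261 for 28 genes with the floor at the 25th percentile, 59 at the 75th, 56 with no floor, 38 with the median over probe sets, 16 with the suffix filter and 1 under quantile normalization. Signal over background is the limit, since the folds of the 601 and 566 genes at the floor on 1 array are bounds. Where the setting shows no cause, the cause was not tested.

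Genes at least 2-fold higher in J3T-2 numbered 438 under quantile normalization and 438 under loess, against 687, and those higher in J3T-1 467 and 465, turning the excess over. The counts for J3T-2 and J3T-1 were 1510 and 869 with the floor at the 25th percentile and 264 and 121 at the 75th, with more and fewer genes measured (13387 and 5236), and the probe set spread was 0.43 and 0.165. All list medians here are plain log2 ratios. A list is called moved when its change exceeds 0.5 times the width of its random range. Centring on the median takes 0.167 from every list, and by that measure moved hypoxia (-0.49), extracellular matrix (0.45), cell cycle (0.08), stress of the endoplasmic reticulum (-0.13) and ribosomal proteins (-0.14). The last 2 turned sign, as did proteases (-0.12), axon guidance (-0.14), growth factor receptors (-0.14), cholesterol (-0.06), DNA repair (-0.05), and fibroblast growth factors and microglia markers (both -0.04). Centred on the hybridization controls the first 5 were -0.50, 0.45, 0.08, -0.14 and -0.14. Quantile normalization gave extracellular matrix 0.44, proteases -0.18, cell-cell adhesion -0.30, axon guidance -0.19, mesenchymal genes -0.37 and cell cycle 0.07, and loess gave extracellular matrix 0.45, proteases -0.18, cell-cell adhesion -0.30 and cell cycle 0.08. Quantile normalization and loess left the same 13 lists outside the random range; the centrings add a constant and cannot move a list's place.

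The floor at the 25th percentile gave angiogenesis-promoting ligands -0.41, axon guidance 0.28, neuron markers -0.22 and fibroblast and pericyte markers -0.12; angiogenesis inhibitors, endothelial markers and TGF-beta and BMP genes came inside the random range. At the 75th percentile angiogenesis inhibitors (0.09, or -0.06 relative to all genes, 6 genes) and chemokines (0.05, or -0.10, 7 genes) reversed, and integrins were at -0.43. With no floor and a pseudocount of 16, which draws dim genes towards 0, the medians were angiogenesis-promoting ligands -0.13, angiogenesis inhibitors -0.06, extracellular matrix 0.15, proneural genes 0.21, neuron markers -0.07, fibroblast and pericyte markers -0.02, Wnt 0.18 and homeobox genes 0.03; angiogenesis inhibitors, extracellular matrix, endothelial markers and chemokines came inside the range. Without _x_at and _s_at probe sets they were angiogenesis-promoting ligands -0.36, extracellular matrix 1.02, proneural genes 1.61, fibroblast and pericyte markers 1.05 and ribosomal proteins 0.13, over fewer genes. Without chromosomes 9, 10 and 14 they were extracellular matrix 0.39 and homeobox genes 0.90. Newly outside were growth factor receptors (25th percentile, suffix filter), integrins (75th percentile, median over probe sets, without the 3 chromosomes), fibroblast and pericyte markers (75th percentile, suffix filter), ribosomal proteins (75th percentile), neuron markers (no floor), proteases (median over probe sets), cell cycle (median over probe sets, suffix filter) and homeobox genes (median over probe sets, without the 3 chromosomes).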

Other observations

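Of the tests in this part, all but that of gene density were chosen, or had their bounds set, after the result was seen. ERK pathway target genes were lower in J3T-2, with a median log2 ratio of -0.87 relative to that of all genes over 17 measured genes, 6 of them at least 2-fold higher in J3T-1 and 0 in J3T-2. UPP1 was 2.75-fold, IER3 2.73-fold, JUNB at least 2.55-fold and HMGA1 2.35-fold higher in J3T-1, while EGR1 (1.8-fold), FOS (1.77-fold) and ETV5 (log2 ratio 0.47) were higher in J3T-2. NF-kB target genes had a relative median of -0.22 over 21 genes, inside the random range (percentile 3.31), with the survival genes BCL2A1 (5.57-fold) and BIRC3 (3.4-fold) and the proteoglycan gene SDC4 (3.37-fold) higher in J3T-1 and the NF-kB subunit gene REL (2.92-fold) higher in J3T-2. The p53 target genes other than CDKN1A had a relative median of -0.22 (percentile 2.45, 23 genes), with PLK2 at least 8.32-fold higher in J3T-1 and SESN1 (4.66-fold), FDXR (2.44-fold) and BTG2 (2.05-fold) higher in J3T-2. Some members also belong to the lists above. These genes were named after their values were seen, and the 3 lists were drawn up after the named genes had been seen. Among unnamed probe sets above the floor (5360), 456 were at least 2-fold higher in J3T-2 and 198 in J3T-1.

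The median log2 ratio of all measured genes was 0.167. A candidate explanation is a difference in the overall brightness of the arrays, which the hybridization controls, added in fixed amounts, can show. Their median log2 ratio over 27 probe sets was 0.17 (SD 0.105), as that explanation needs. No biological explanation was tested for this shift, and after centring 51.9% of the 2-fold calls were higher in J3T-2, against 48.4% under quantile normalization and 48.5% under loess.

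Chromosomes 9, 10 and 14 deviated from the median of the others (0.13) by 0.48, 0.46 and -0.45, while the other 36 deviated by -0.14 to 0.13. A bias that depends on signal strength is argued against by loess, after which the smallest deviation was 0.44, and gene density by its line over the other chromosomes, from which these 3 lay at least 6.9 residual SDs away, although chromosome 9 is denser than any other and GC content itself was not tested. A different copy number of these chromosomes in the subclones may account for the pattern: cut by gene order into 4 parts, each chromosome deviated the same way in every part, by at least 0.35, and 3 copies against 2 would give 0.58 in DNA. This is a hypothesis, found and tested on the same 2 arrays, and it does not say which subclone differs from the parental line.

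The lists of angiogenesis-promoting ligands, of chemokines, cytokines and complement and of hypoxia-inducible genes were higher in J3T-1, although the first 2 share CXCL8 and CCL2 and the second came inside the random range with the floor at the 75th percentile (20.98) and with no floor (2.67). Higher ERK pathway activity in J3T-1 could account for it, although nothing tested ties that activity to these lists. The 11 ERK target genes outside the main lists lay at percentile 0.0, with 9 below the median of all genes and EGR1 and FOS above. Their relative median was -1.32, against -0.87 for all 17. All 6 members at least 2-fold apart stayed among the 11, while those left out, such as ETV5 (log2 ratio 0.47), were within 2-fold. The wider shift thus follows from which members were left out and adds nothing for this explanation. IER3 also counts among the NF-kB targets. The values of the 11 genes had been seen. The 21 such p53 target genes, for which no such explanation was weighed, lay at percentile 0.09 as well. For higher NF-kB activity the 15 such targets lay at percentile 2.87, between the bounds. Lower oxygen in the J3T-1 culture is argued against by the 22 further hypoxia-inducible genes outside the lists, for the genes they cover. Their relative median was -0.03, at percentile 39.12, past the bound first set against lower oxygen (25). Of them, 11 lay above and 11 below the median of all genes. A second condition, set after this was seen, asked that their distance from the median of the hypoxia list exceed their SD. The distance was 0.47 and the SD 0.49, but an SD of single genes is not the error of a median. That condition therefore decides nothing. The 22 genes showed no shift outside the random range while the hypoxia list did. They leave out members of the main lists and the named genes. With 1 culture each, a stable difference between the subclones and the state of the culture remain open alike.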
